A study of Homo sapiens with 6 samples.

How the data were processed

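ATAC-seq was run on 2 samples each of undifferentiated KOLF2.1J iPSCs, day 18 microglia-like cells and day 18 microglia-like cells given LPS and IFNG, and groups were taken from the sample titles. The titles give the LPS dose in mg/ml and the treatment protocol in ng/ml. The protocol's unit is used here. Per the submitters' processing notes, the tools were cutadapt, Bowtie2, Picard, SAMtools and MACS2 with genome build hg38, and their versions and settings are not given in the sources used here. Whether reads were shifted for the transposase offset is likewise not given.

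The deposited data used are 1 narrowPeak list per group with 10 columns and no header. Each peak has the authors' own score, which is 10 times −log10 p capped at 1000, a deposited fold enrichment ratio over local background, and deposited −log10 values of p and q. The peak names are ranks by p that reach 300000 in the iPSC list, and 90.0%, 83.1% and 83.5% of ranks are present in the iPSC, untreated and stimulated lists. The lists are therefore limited by rank and their weakest peaks differ in significance. The authors' fold, score and −log10 values were used to describe, rank or filter peaks within a list. In added steps folds were also set against each other between lists, by 1 fold limit for both lists and by the median fold ratio of shared regions, although the folds are not scaled between lists. How replicates entered each list was not given beyond a name that speaks of overlap, so each list was treated as a pooled result for its group.

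Overlapping or touching peaks were merged into regions, since 49.4%, 53.1% and 51.3% of regions in the iPSC, untreated and stimulated lists held several peaks. A region was shared if it overlapped a region of the other list by at least 1 bp, and otherwise list-only. Strong regions were those in the top 25% of their own list by fold. Shares carry Wilson 95% intervals, which cover counting error only. Each list is 1 value per group, so no test with replicates of the conditions was run. The permutation p of the gene density trend in the closing section takes 22 chromosomes as units and describes the 2 lists, not the conditions.

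Genes came from a RefSeq table of the same build with 20037 protein-coding genes on the main chromosomes. It was used without strand, exons or sequence, which changed 4 planned steps. The planned promoter became a window of 1 kb around either annotated gene end. Any overlap with that window counted as near a gene end, where the plan used the region's midpoint. The nearest transcription start became the nearest protein-coding gene interval within 100 kb, exon and intron classes became inside or between genes, and motif shares were not run. A planned check for reads of the transgene in coding exons was also not run. Before the data were examined, 17 gene lists with 454 entries were fixed, and 453 entries matched (TDGF1 under its current symbol CRIPTO, TRBC1 not matched). For each list, the mean difference in list-only regions per gene was set against 10000 random lists of the same size matched in 10% steps on the total number of regions, and a list in the outer 2.5% on either side was said to stand apart. This gave 34 percentiles over 2 comparisons.

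Named genes follow a rule fixed before the data were examined. For each direction it takes the nearest genes of the 10 list-only regions of highest fold, the 5 genes with the largest net number of list-only regions, and up to 4 members of each list with a gene-end region in that list only. SPI1, CEBPA, CEBPB, IRF5, IRF8, POU5F1, SOX2, NANOG, CSF1R, P2RY12, TMEM119, TREM2, CXCL10 and IL1B are named whatever their values. A few genes that the rule takes are left out of the text. CLYBL and the class II HLA and cytokine genes set side by side in the closing section were picked after their values had been seen.

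In all, 42 alternatives were planned and 14 were added after seeing the data. Of the planned ones, 5 were not run, namely 4 for motifs and 1 for other annotated transcription starts. The planned ones included floors of 2 and 5 on −log10 q, which removed no peak. The added ones were floors of 15 and 30 on −log10 p, 1 fold limit for both lists, assignment to the nearest gene end, region balances of strong regions alone (34 percentiles) and percentiles of gene-end calls (34 percentiles). The location of strong list-only regions and the comparison of CLYBL with other genes were also looked at only after seeing the data.

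The overlap and percentile steps were tested on simulated data. In a list simulated from the iPSC regions all 8206 planted and 56709 removed regions were recovered by count. In a list simulated from the untreated microglia regions all 8844 and 50385 were. Regions were not matched 1 by 1, and a count above the number removed was taken as 100%. Of 200 simulated lists of 30 genes with no shift, 6% stood apart in the first simulation and 7.5% in the second, against a nominal 5%. With a shift of 2 regions per gene on average, which is a large effect, 100% did. The planted regions lay far from other regions, so their recovery checks the overlap step alone. Gene counts in these simulations were drawn independently and not from the real lists, so the shares may not hold for the real counts. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.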

Results

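Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters. The 6 samples came from KOLF2.1J, an established human induced pluripotent stem cell (iPSC) line. The samples are titled iTF-iPSCs or iTF-Microglia and carry a knock-in of inducible transcription factors at the CLYBL locus. They form 3 groups of 2 samples: undifferentiated iPSCs, microglia-like cells at day 18 of differentiation, and day 18 microglia-like cells given 100 ng/ml lipopolysaccharide (LPS) and 20 ng/ml interferon gamma (IFNG) for 24 h. One peak list per group was analysed, so no value has a spread between replicates, no difference between conditions could be tested, and the sequencing depth is unknown. After merging of touching peaks, the iPSC list held 141293 regions over 116.6 Mb, the untreated microglia list 126083 regions over 112.5 Mb and the stimulated microglia list 129613 regions over 111.6 Mb. The weakest peak had a −log10 p of 14.4 in the iPSC list, 7.55 in the untreated list and 7.51 in the stimulated list. The stricter floor of the iPSC list means that a microglial region absent from it may still have had signal in iPSCs.

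The first comparison asked which open regions separate iPSCs from the microglia-like cells derived from them. Genes of the pluripotency list were called on the iPSC side alone or in both lists, and none on the microglial side alone. Of its 30 members, 9 had a region within 1 kb of an annotated gene end only in the iPSC list, 20 in both lists and 1 in neither. DPPA2 and NANOG had the highest fold enrichment at such an end in iPSCs, 9.88 and 9.23, followed by USP44 (5.93) and LIN28A (5.40), an RNA-binding protein of pluripotent cells. POU5F1, which encodes the pluripotency factor OCT4, had an iPSC region of fold 2.64 near its end at position 31170682 of chromosome 6 and no microglial region there. SOX2, another pluripotency factor that is also used in neural cells, had a gene-end region in all 3 lists.

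NANOG lies on chromosome 12 from 7789402 to 7799146 (hg38). The iPSC list held 3 regions assigned to it, and neither microglia list held any. P2RY12, a purinergic receptor of homeostatic microglia on chromosome 3 from 151336843 to 151384753, showed the opposite arrangement. It had 5 regions assigned in untreated microglia, all absent from the iPSC list, and a further region of fold 6.81 across its upper end, from 151384637 to 151385117, whose midpoint lies beyond the gene. A single iPSC region of fold 7.44, from 151379000 to 151379669 inside the gene, was not called in microglia.

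**Figure D1:**
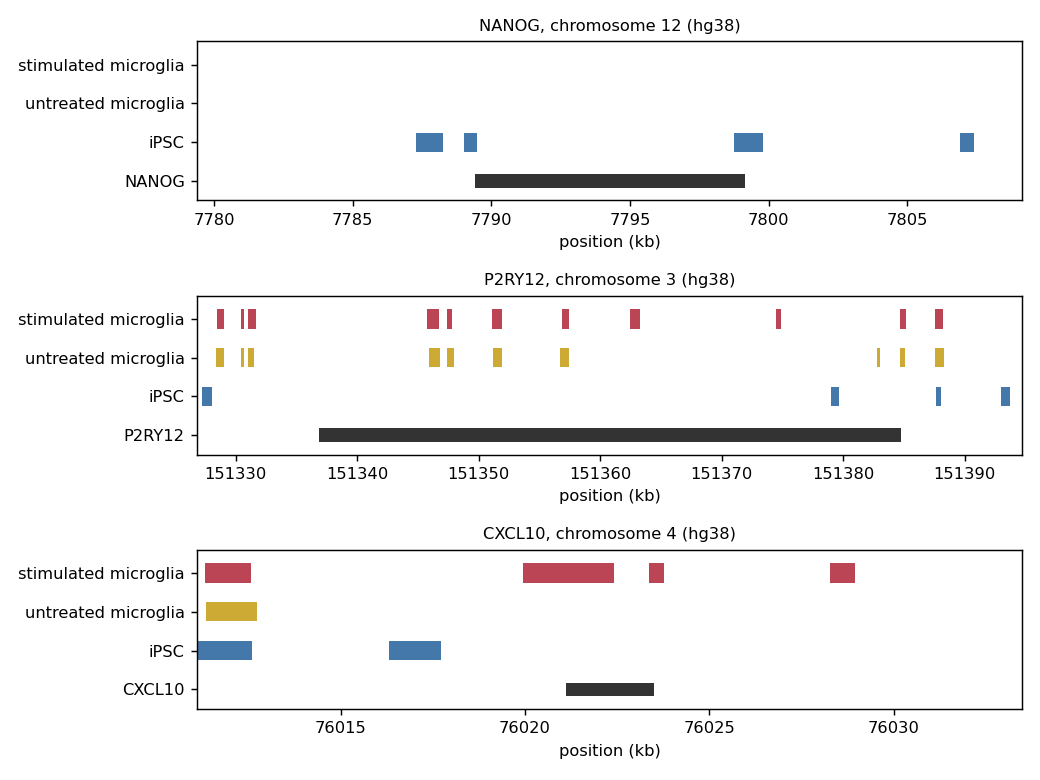
Regions called in each of the 3 lists around NANOG, P2RY12 and CXCL10, with each gene's annotated extent as a dark bar. The horizontal axis gives the hg38 position in kb, and each coloured bar is 1 merged region drawn to scale. NANOG has regions only in the iPSC list, and the regions overlapping CXCL10 itself are only in the stimulated list.

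Broader myeloid genes were called in microglia more often than in iPSCs, whereas the microglia identity list was not one-sided. Of 32 pan-myeloid genes, 6 had a gene-end region only in untreated microglia and 3 only in iPSCs. PTPRC, which encodes the leukocyte antigen CD45, had fold 6.63 at a gene end and 17 microglia-only regions. MS4A7 (6.34), the co-stimulatory receptor gene CD86 (5.63) and LAPTM5 (5.46) followed. In the microglia identity list of 36 genes, 3 (P2RY12, AIF1 and ADORA3) were called only in microglia and 5 only in iPSCs, among them C1QA (4.47), TMEM119 (4.12), FCGR1A (3.85) and CD33 (3.69). A 500 bp window turned this direction, with 8 only in microglia and 4 only in iPSCs. With a shared −log10 p floor of 15, added after seeing the data, 8 were called only in iPSCs. The microglia-only count then stayed within 1.5 times of the first. CSF1R and TREM2, a growth factor receptor and a lipid-sensing receptor of microglia, had a gene-end region in both lists. The gene-end window can cover either end of a gene or the promoter of a neighbour, since strand was not used here.

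SPI1, CEBPA, CEBPB, IRF5 and IRF8, transcription factors used in the differentiation system, had a gene-end region in all 3 lists. SPI1, which encodes the myeloid factor PU.1, had 3 regions assigned in iPSCs and 4 in each microglia list. By single end, its lower end was called in all 3 lists. Its upper end was called only in untreated (2.30) and stimulated (2.65) microglia. An iPSC region of fold 2.81 ended at position 47377337 of chromosome 11, outside that window. IRF8 had 11 regions in iPSCs, 7 in untreated and 6 in stimulated microglia. The interferon list of 52 genes had 9 members called only in untreated microglia and 2 only in iPSCs. The antiviral genes MX2 (fold 5.80) and IFI44 (5.76), the immune checkpoint ligand gene PDCD1LG2 (5.73) and the GTPase gene GBP2 (4.77) were among the 9, and APOL6 and IFITM1 were the 2. At a shared −log10 p floor of 15, added after seeing the data, the counts were 7 and 5. The antigen presentation list had 5 of 30 members only in iPSCs, with HLA-DRA (11.998) and HLA-DOA (11.1) highest, and 1, CD86, only in microglia.

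The LPS and NF-κB list held microglia-only regions above the level of random lists. Its 48 genes had 177 microglia-only and 111 iPSC-only regions assigned, a mean difference of 1.375 regions per gene against a median of −1.02 in 10000 random lists matched on total regions, at the 99.99th percentile. At gene ends the same list was nearly even, with 6 members only in microglia, such as IL7R (7.54) and ACOD1 (4.58), and 7 only in iPSCs, such as IL27 (6.85) and IL23A (5.64), and a 500 bp window turned this to 7 and 6. The pan-myeloid list also stood above random lists, with 130 microglia-only and 104 iPSC-only regions at the 98.2 percentile. The endoderm and hepatocyte marker list stood below them, with 28 and 104 regions at the 0.84 percentile. Both of these calls ended with strong regions alone, added after seeing the data (93.4 and 8.76 percentiles), and the endoderm call also with the 50000 regions of highest fold per list (45.2). The other 14 lists did not stand apart, including pluripotency at the 10.1 percentile with 66 microglia-only and 143 iPSC-only regions, and microglia identity at the 51.9 percentile. Lymphoid markers, at 2.74, passed the limit with 50000 regions per list, gene body plus 10 kb and no matching, and with 2 added settings. Gene body plus 10 kb also brought microglia identity and the interferon list past it, and no matching the neural progenitor and glial list. With 34 such percentiles over both comparisons, 1.7 would stand apart by chance. These percentiles describe the lists and do not test the conditions. A percentile for gene-end calls, added after the counts had been seen, lay at 0.025 for pluripotency, 0.01 for neuronal and 0 for neural progenitor and glial markers, and at 99.3 for pan-myeloid, 100 for interferon and 99.3 for Alzheimer risk genes. These percentiles were not computed at a shared floor.

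Marker lists of other cell types had no more genes called only in microglia than only in iPSCs. Of 20 neuronal markers, 7 had a gene-end region only in iPSCs, such as RBFOX3 (10.1) and DCX (5.79), and none only in microglia. The neural progenitor and glial list likewise had 7 and 0 of 20, including ALDH1L1 (7.22) and OLIG2 (6.58). Lymphoid markers were called for 6 genes only in iPSCs, such as CD79B (4.86), and for 3 only in microglia, CD2, GNLY and CD79A. Mesenchymal and endothelial markers gave 4 and 1, granulocyte, mast cell, erythroid and megakaryocyte markers 4 and 3, and endoderm markers 2 and 0. All 24 cell cycle and all 25 housekeeping genes were called in both lists. Over all 20037 protein-coding genes, 1667 (8.32%) had a gene-end region only in iPSCs and 604 (3.01%) only in untreated microglia. Lymphoid markers (31.6% and 15.8%), the granulocyte group (20% and 15%) and mesenchymal and endothelial markers (20% and 5%) exceeded both of these shares. The pan-myeloid list had 9.38% and 18.8%.

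Among Alzheimer disease risk genes, 5 of 31 had a gene-end region only in untreated microglia and 2, CD33 and MEF2C, only in iPSCs. CASS4 (8.35), MS4A4A (6.56), BLNK (6.46) and MS4A6A (4.01) were the microglia-only members of highest fold. At a shared −log10 p floor of 15, added after seeing the data, 5 were called on each side. The list of homeostatic microglial genes had 4 of 22 only in iPSCs (FOLR2, TMEM119, FCGBP and MEF2C) and P2RY12 only in microglia, against 3 on each side with a 500 bp window.

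In total, 85321 iPSC regions (60.4%, Wilson 95% interval 60.1 to 60.6) overlapped no region of untreated microglia, and 70948 microglial regions (56.3%, 56.0 to 56.5) overlapped none of the iPSC list. The intervals cover counting error only. At a shared −log10 p floor of 15, added after seeing the data, the counts were 95154 and 46696, and at 30 they were 73147 and 27377. Among regions in the top 25% of their own list by fold enrichment, 9302 of 35324 (26.3%) were iPSC-only and 12507 of 31530 (39.7%) microglia-only. With 1 fold limit for both lists, added after seeing the data, the microglia-only count was 5546 and no longer exceeded the iPSC-only count. List-only regions lay away from gene ends. Of iPSC-only regions 4.85% (4.71 to 5.00) lay within 1 kb of a gene end and of microglia-only regions 2.14% (2.04 to 2.25), against 25.3% and 25.1% of the shared regions.

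The iPSC-only regions of highest fold included 1 inside LRP1B (fold 19.2, chromosome 2 from 140905046 to 140905863), 1 inside TMEM131 (18.1) and 1 inside ABCB4 (17.9). Regions near ZNF648, ITPRID2 and GC were also among the 10 of highest fold, and 4 of these 10 had no protein-coding gene within 100 kb. The corresponding microglia-only regions lay inside PGGT1B (17.0), CEP152 (17.0), ADGRB3 (17.0) and SYT1 (16.7), among others, with 5 more than 100 kb from any such gene. The genes with the largest net number of iPSC-only regions were SHANK2 (61 against 4), GSE1 (59 against 4), SDK1 (59 against 6), CAMTA1 (56 against 5) and DAB1 (82 against 34). For microglia-only regions they included GALNT13 (69 against 29), PCDH15 (57 against 17), LRP1B (72 against 35) and FHIT (68 against 33). These genes span between 506689 and 1899594 bp, so their counts also reflect their length.

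**Figure D2:**
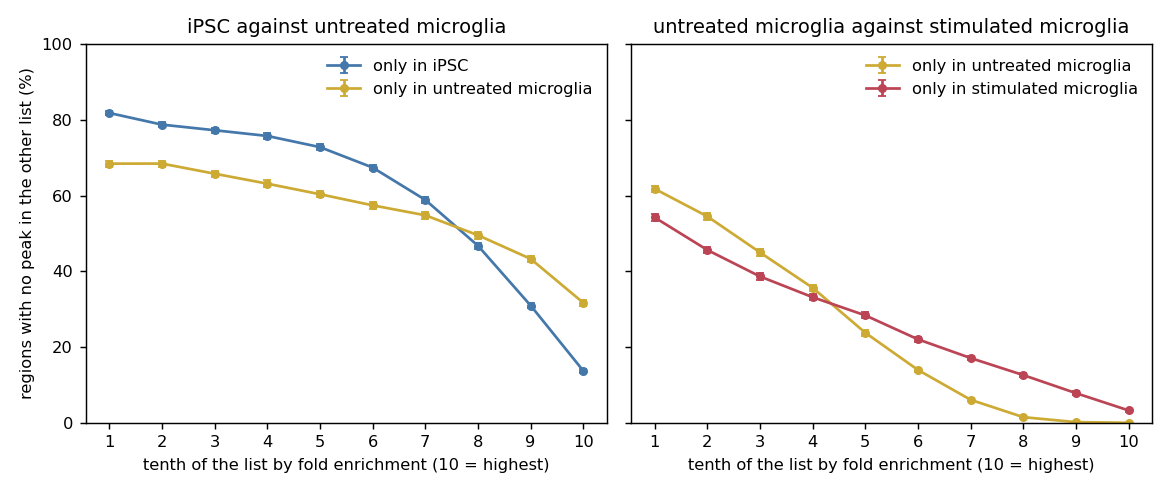
Percent of regions with no peak in the other list (vertical axis) for successive 10% steps of a list by fold enrichment (horizontal axis), with Wilson 95% intervals that are mostly smaller than the points. In the right panel the share in the strongest 10% is 0 for the untreated list and 3.26% for the stimulated list.

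The second comparison asked which regions differ between untreated microglia-like cells and those given LPS and IFNG. Interferon, antigen presentation and inflammatory genes had gene-end regions only in the stimulated list more often than only in the untreated list. The stimulated-only members named below from these lists had gene-end folds from 2.74 (CCL8) to 4.78 (CXCL10). All were under that list's limit for strong regions (5.45), and they lay on both sides of its median region fold (3.55). In the 10% steps by fold holding 2.74 and 4.78, 38.6% and 17.1% of stimulated regions were stimulated-only. A threshold effect therefore stays undecided for these calls. In the interferon list, 6 of 52 genes were called only after stimulation and 0 only before. With a shared −log10 p floor of 15, added after seeing the data, 10 were called only after stimulation. CXCL10 and CXCL11, chemokines induced by interferon gamma, had fold 4.78 and 4.74 at a gene end, and APOL1 and APOL3 had 4.59 and 4.13. CXCL10 lies on chromosome 4 from 76021118 to 76023497 and was overlapped by stimulated-only regions from 76019951 to 76022427 and from 76023359 to 76023780.

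In the antigen presentation list, 6 of 30 genes were called at a gene end only after stimulation, 24 in both lists and 0 only in untreated cells. HLA-DRA (4.28), HLA-DOA (4.01) and HLA-DQA1 (3.20), which encode chains of class II molecules or their relatives, had the highest values, followed by the protease gene CTSS (3.05). In the LPS and NF-κB list, 6 of 48 genes were called only after stimulation, including IL27 (4.34) and EBI3 (4.14), which encode both chains of 1 cytokine, and the chemokine genes CCL5 (3.09) and CCL8 (2.74). CSF3 was called only in the untreated list, at fold 2.05. IL1B was called in both lists, at 2.59 and 2.71. Over all protein-coding genes the calls were nearly even, with 440 only in the stimulated list and 468 only in the untreated list.

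In the microglia identity list, no gene had its gene-end call, taken over both ends, in the untreated list alone. Of its 36 members, 4 were called only after stimulation, C1QA (3.63), FCGR1A (3.29), SLCO2B1 (2.73) and TMEM119 (2.48). None were called only before, or 2 with a 500 bp window. The 4 folds were also under the limit for strong stimulated regions (5.45), so a threshold effect stays undecided for them too. P2RY12 and CSF1R were called in both lists, with 5 and 6 regions assigned to P2RY12 and 8 and 10 to CSF1R. TREM2 had 3 regions in untreated and 1 in stimulated cells and kept a gene-end call in both, at its lower end (2.30 and 2.31). A region at its upper end was called only in untreated cells (2.58). By single end CSF1R went the other way, with a lower-end region only in stimulated cells (2.16). The homeostatic list had 1 of 22 members, TMEM119, only in the stimulated list, and at a shared −log10 p floor of 15, added after seeing the data, 0 there and 2 only in the untreated list. Pan-myeloid genes gave 3 only after stimulation (CYBB, CTSS and FLI1) and 2 only before (RUNX1 and ITGB2). Pluripotency genes gave 0 and 2 (LEFTY2 and CDH1), and no Alzheimer risk, cell cycle or housekeeping gene and none of the differentiation factors differed in call. A 500 bp window gave 1 Alzheimer risk gene on each side. The added floor of 15 gave 2 Alzheimer risk genes after and 1 before, 1 differentiation factor after and 1 pluripotency gene before. Markers of other cell types differed for few genes, with ELAVL3 and SLC1A3 only after stimulation in the 2 neural lists, 2 lymphoid genes (CD79B and CD3D) after and CD2 before, KLF1 after and CEBPE before, 2 endoderm genes on each side and 0 mesenchymal genes.

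**Figure D3:**
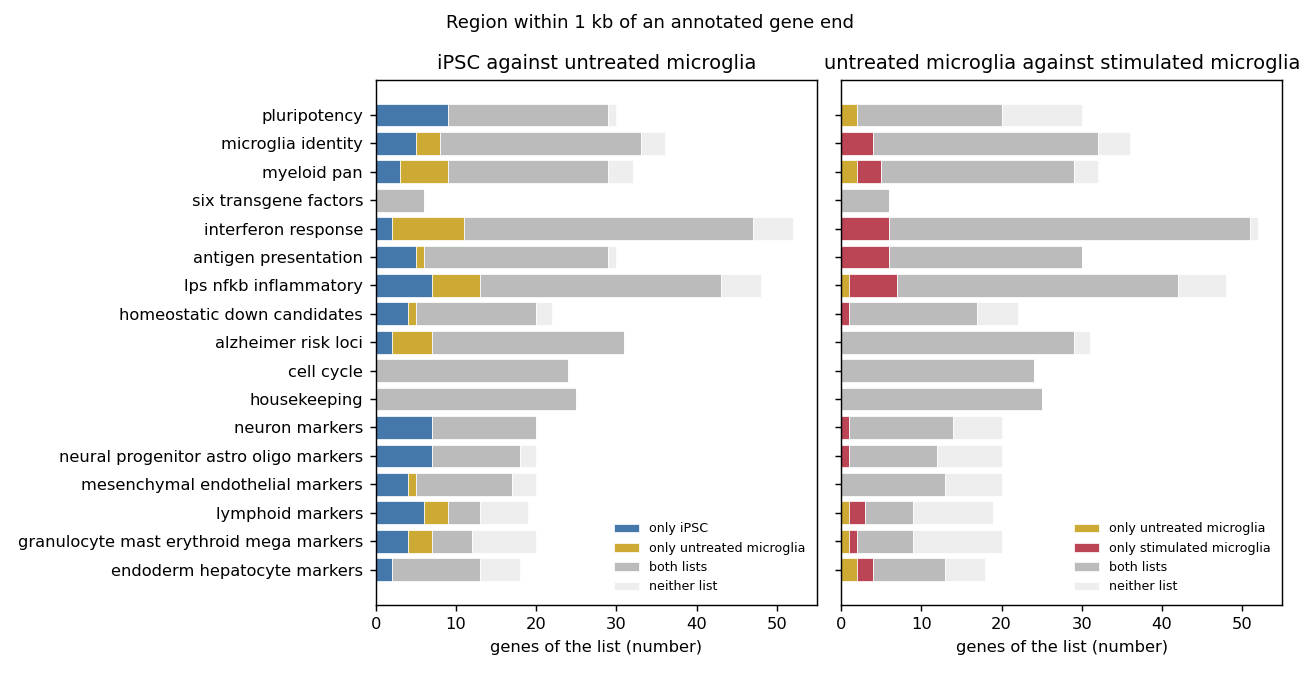
Number of genes in each list fixed before the data were examined (horizontal axis) that had a region within 1 kb of an annotated gene end in 1 list only, in both lists or in neither. In the right panel the interferon and antigen presentation lists each have 6 genes called only after stimulation and 0 called only before.

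Counted over all assigned regions, the planned measure for gene lists, no list stood apart from matched random lists in this comparison. The interferon list had 53 stimulated-only and 30 untreated-only regions, at the 97.4 percentile, which did not pass the limit. Antigen presentation had 23 and 11 (94.6) and the LPS and NF-κB list 80 and 44 (92.8). Lists that were not chosen for a link to the stimulus lay as high, with cell cycle genes at the 96.5 percentile (16 and 4 regions) and housekeeping genes at 96.2 (17 and 3). Whether the stimulus acts on those genes was not tested. These calls depend on the setting. The interferon list passed with 50000 regions per list, the LPS and NF-κB list with the gene body and with no matching, cell cycle genes with the gene body, lymphoid markers with 50000 regions and mesenchymal markers, on the untreated side, with no matching. With settings added after seeing the data, interferon passed at a −log10 p floor of 15 and with the nearest gene end, and antigen presentation at that floor. A percentile for the gene-end calls was added after these results had been seen. On it the interferon list lay at 99.955, antigen presentation at 100, LPS and NF-κB at 99.85 and microglia identity at 99.685, and cell cycle and housekeeping genes, all called in both lists, could not stand apart on it. Because this measure was chosen after the planned one had put no list apart, it is a lead for a new data set. Neighbouring genes such as those of the HLA cluster are also not independent of each other.

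Of the untreated regions 30548 (24.2%, 24.0 to 24.5) overlapped no stimulated region, and of the stimulated regions 34054 (26.3%, 26.0 to 26.5) overlapped no untreated region. Among regions in the top 25% of their list, 83 of 31530 (0.263%, 0.212 to 0.326) were untreated-only and 2131 of 32404 (6.58%, 6.31 to 6.85) stimulated-only. These counts were 698 and 2995 under reciprocal overlap, 463 and 4531 by single summits, and 22 and 2131 with 1 fold limit for both lists, which was added after seeing the data. Within 1 kb of a gene end lay 2.83% of untreated-only and 3.02% of stimulated-only regions, against 15.2% of shared regions in each list.

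Of the 10 stimulated-only regions of highest fold, 6 had no protein-coding gene within 100 kb. The others were 1 near SHOC2 (fold 16.6, chromosome 10 from 111029755 to 111030843), 1 inside CNTLN (16.1), 1 inside SLC35F5 (16.1) and 1 inside MAP3K19 (15.5). Over all 2131 strong stimulated-only regions, looked at after seeing the data, 24.3% had no such gene within 100 kb. This share was 22.4% of all stimulated regions and 15.1% of strong shared ones. The untreated-only regions of highest fold included 1 inside PGAP1 (6.88), 1 inside PTAR1 (6.74), 1 inside RALGAPA1 (6.31) and 1 inside LRMDA (6.02), with others near UCHL5, ANKIB1 and PRKG1. Large net numbers of stimulated-only regions were at TENM3 (37 against 19), ERBB4 (38 against 20), AUTS2 (28 against 10) and GRM8 (28 against 11). Those of untreated-only regions were at ANK2 (28 against 8), FHIT (34 against 15), NELL1 (20 against 7) and KCNIP4 (17 against 4). All of these are long genes.

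Placing the 3 lists together gave 237319 merged regions. All 3 lists shared 47314 of them (19.9%), 78387 (33.0%) were in iPSCs alone and 47264 (19.9%) in both microglia lists but not in iPSCs. Regions in stimulated microglia alone numbered 27360 (11.5%) and those in untreated microglia alone 22976 (9.68%). Compared directly, 86327 iPSC regions were absent from the stimulated list and 75280 stimulated regions from the iPSC list. A further 7460 were shared by iPSCs and untreated microglia only, and 6558 by iPSCs and stimulated microglia only. Of the stimulated-only regions of the second comparison 19.7% overlapped an iPSC region, and of the untreated-only regions 24.8%. The shared regions did so in 49.9% and 49.8% of cases, or 42.7% and 41.7% when weighted to the fold distribution of the list-only regions.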

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

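The settings on −log10 p, the single fold limit, the nearest gene end and the strong regions alone were chosen after seeing the data. No paired analysis was possible because each group has 1 peak list and no values per replicate, and leaving out a replicate was not possible for the same reason. Floors of 2 and 5 on −log10 q removed no peak, so they say nothing about stability, and chromosomes 1 to 22 alone kept every region count within 1.5 times. The cause of each shift below was not tested, except that shorter lists and single peaks change counts by construction. Depth is unknown and limits which weak regions could be called. Apart from those floors, region balances kept their call in 89 planned and 95 added cases, 12 and 5 newly passed the limit and 1 and 2 no longer did. Gene-end counts stayed within 1.5 times in 110 planned and 48 added cases and moved in 26 and 20. The 5 alternatives on motifs and other transcription starts were not run.

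With the 50000 regions of highest fold per list, iPSC-only and microglia-only regions numbered 28636 and 28697 with 21364 shared, and untreated-only and stimulated-only regions 11491 and 11535 with 38509 shared. Counting single peaks by summit gave 137078 iPSC-only and 122637 microglia-only with 132961 shared, and 205395 shared between the microglia lists. Strong counts by summit were 18769 iPSC-only, 23039 microglia-only, 463 untreated-only and 4531 stimulated-only. Reciprocal overlap gave 698 strong untreated-only and 2995 strong stimulated-only regions. One fold limit gave 22 strong untreated-only and 5546 strong microglia-only regions. At −log10 p of 15, microglia-only regions against iPSCs were 46696, untreated-only regions 18693 and regions in untreated microglia alone 13249. At 30, the untreated and stimulated lists held 55710 and 62693 regions, with 27377 microglia-only and 28927 shared against iPSCs, and 9372 untreated-only, 16338 stimulated-only and 46338 shared between the microglia lists.

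Region balances are given as the excess over the median random list, in regions per gene. For untreated microglia against iPSCs, lymphoid markers passed the limit with 50000 regions (−1.16), gene body plus 10 kb (−2.58), nearest gene end (−2.16), no matching (−2.32) and strong regions (−0.684). Gene body plus 10 kb also brought microglia identity (1.36) and the interferon list (0.692) past it, and no matching the neural progenitor and glial list (−2.35). Endoderm markers lost the call with 50000 regions (−0.0556) and with strong regions (−0.389), as did pan-myeloid genes with strong regions (0.375). For stimulated against untreated cells, the interferon list passed at −log10 p of 15 (0.423), with 50000 regions (0.231) and with the nearest gene end (0.385), and not with the gene body, no matching or strong regions. Antigen presentation passed at −log10 p of 15 (0.40), the LPS and NF-κB list with the gene body (0.438) and no matching (0.563), cell cycle genes with the gene body (0.50), lymphoid markers with 50000 regions (0.474) and mesenchymal markers with no matching (−0.75).

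The share near a gene end was, with a 2 kb window, 7.56% of iPSC-only and 28.0% of shared iPSC regions, 3.69% of microglia-only and 27.6% of shared microglial regions, 4.47% of untreated-only and 17.3% of shared untreated regions, and 5.02% of stimulated-only and 17.3% of shared stimulated regions. At −log10 p of 15 these were 5.10%, 29.5%, 2.33%, 29.3%, 3.55%, 18.6%, 3.63% and 18.6% in the same order, and the order of list-only below shared held in both.

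Gene-end counts are small and moved easily. For iPSC against untreated microglia, a 500 bp window gave 8 microglia identity genes only in microglia and 4 only in iPSCs, 3 homeostatic genes only in microglia and 1 of the differentiation factors only in iPSCs. A 2 kb window gave only in iPSCs 1 pan-myeloid, 4 neural progenitor and glial and 2 mesenchymal genes, and only in microglia 0 mesenchymal and 1 endoderm gene. At −log10 p of 15, the iPSC-only counts were 8 microglia identity, 1 of the differentiation factors, 5 interferon, 5 Alzheimer risk and 4 endoderm genes, with 0 mesenchymal genes only in microglia. For untreated against stimulated cells, a 500 bp window gave only in untreated cells 2 microglia identity, 2 LPS and NF-κB, 1 homeostatic, 1 Alzheimer risk and 0 granulocyte-group genes, and only in stimulated cells 1 Alzheimer risk, 0 neuronal, 0 neural progenitor, 1 lymphoid and 0 granulocyte-group genes. A 2 kb window gave only in untreated cells 1 pan-myeloid, 1 mesenchymal and 1 endoderm gene, and only in stimulated cells 1 pan-myeloid, 2 neuronal, 0 neural progenitor, 5 lymphoid and 1 endoderm gene. At −log10 p of 15, the untreated-only counts were 1 pluripotency, 1 microglia identity, 0 LPS and NF-κB, 2 homeostatic, 1 Alzheimer risk and 1 endoderm gene, and the stimulated-only counts 1 of the differentiation factors, 10 interferon, 0 homeostatic, 2 Alzheimer risk, 3 neural progenitor, 1 mesenchymal, 0 lymphoid and 0 endoderm genes.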

Other observations

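The tests of strong stimulated-only regions were chosen after the result was seen, and the bound for gene density was set after the chromosome shares had been seen but before its value was computed. Of the 9 class II HLA genes in the antigen presentation list, 5 were called at gene ends in iPSCs and after stimulation but not in untreated microglia, and the other 4 (HLA-DRB1, HLA-DPA1, HLA-DMA and HLA-DMB) in all 3 lists. The arrangement was picked after the values had been seen, and 263 of 20037 protein-coding genes (1.31%) have it. HLA-DRA had fold 11.998 at a gene end in iPSCs, no gene-end region in untreated cells and fold 4.28 in stimulated cells. HLA-DOA (11.1 and 4.01), HLA-DQB1 (7.64 and 2.97), HLA-DQA1 (6.57 and 3.20) and HLA-DPB1 (3.73 and 2.96) had the same arrangement. In the LPS and NF-κB list 5 of 48 genes, IL27 (6.85 and 4.34), IL23A (5.64 and 2.45), CCL8 (5.47 and 2.74), CCL5 (5.25 and 3.09) and EBI3 (4.33 and 4.14) did too. The same arrangement was as frequent among lymphoid markers (2 of 19, 10.5%) as in this list (10.4%), and was found for 3 of 36 microglia identity genes (8.33%). These folds come from separate lists and their sizes are not comparable between lists.

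CLYBL, the gene that holds the insertion in these cells, had 45 regions in iPSCs, 17 in untreated and 16 in stimulated microglia. It was looked at after the data were seen. Of 385 genes with 50 to 80 regions over the iPSC and untreated lists, 23 had a net difference at least as far toward iPSCs as its −28, so CLYBL does not stand alone.

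Strong regions called only after stimulation outnumbered those called only before by 25.7 times (2131 against 83), with 2995 against 698 under reciprocal overlap, 4531 against 463 by single summits and 2131 against 22 with 1 fold limit for both lists. Loss of equally strong peaks from the untreated list for lack of replicate overlap would need at least 0.5 times as many absent peaks, but 619 were absent among its 100000 best ranks, against 534 in the stimulated list. A higher fold scale of the whole stimulated list would need a ratio of 2.34 to bring such regions near the untreated floor, but the median over 93676 shared regions was 1.05 (1.02 to 1.12 by chromosome), a measure taken after 2 earlier tests of this explanation were set aside because their outcome was fixed. Regulatory regions of interferon genes may contribute. The 52 genes of the interferon list held 5 of the 2131 such regions, so that list accounts for few of them. It lay at the 95.2 percentile of random lists, which does not decide whether it holds more than its share. The LPS and NF-κB list held 6, at the 40.6 percentile, and the pluripotency list 6, at 90.0. A difference between the cultures or libraries cannot be separated from the stimulus with 1 list per group.

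Regions called in only 1 of the microglia lists were mostly weak. In the strongest 10% of untreated regions 0 of 12609 were untreated-only, in line with peaks that fell just short of the threshold in the stimulated list. In the strongest 10% of stimulated regions 3.26% (2.96 to 3.58) were stimulated-only. That is under the 5% set in advance as evidence against a threshold effect, but it is not near 0 (at most 1%, a limit set after the value was seen), and the median fold of stimulated-only regions (2.80) lay above the lowest 10% of the list (up to 2.40), as did that of untreated-only regions in theirs (2.54 against 2.33), for which no such bound had been set. For the stimulated list as a whole the threshold explanation therefore stays undecided. Its 422 stimulated-only regions in the strongest 10% had folds from 8.34, whereas the lowest 10% of untreated folds ended at 2.33. Shared regions, which had to be called in both lists, differed by a median ratio of only 1.05. If that ratio held for the 422 as well, a signal of like size in untreated cells would lie well above that floor. The 422 have no untreated fold, so how far they fell short of the untreated limit cannot be told.

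Gene-poor chromosomes held relatively more microglial than iPSC regions. Over 22 autosomes, taken as units although they are not replicates of the conditions, the log2 ratio of untreated microglia to iPSC regions fell with gene density. Pearson r was −0.636 (permutation p = 0.00358, adjusted 0.00716). Spearman rho was −0.709 (permutation p = 0.0003, adjusted 0.0012, 8 coefficients computed). Without chromosomes 17 and 19 r was −0.618 and rho −0.624. Weak regions near the lower floor of the microglia list could give such a trend. In the top 25% of each list rho was −0.81 (r = −0.666), past the bound of −0.7 set against it. Without those chromosomes rho there was −0.759 and r −0.671. A gain or loss of a chromosome in 1 culture was not settled. No chromosome exceeded 1.5 times the list-only share of the others (highest 1.19). With list-only shares of 60.4% in iPSCs and 56.3% in untreated microglia, that bound was hard to reach in the first comparison. Chromosomes 19 (0.346), 22 (0.504) and 17 (0.540) lay below the range set in advance for microglia-only regions. So did chromosome 19 for untreated-only (0.531) and stimulated-only regions (0.661). GC content was not tested, so the trend is not called biological.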
